A study of Homo sapiens with 12 samples.

How the data were processed

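The data are RNA sequencing libraries of polyadenylated RNA from MCF7 cells, made with a stranded mRNA kit, per the labels' protocols. Each of 4 groups held 3 libraries: cells with ectopic wild-type MED1 (WT) and cells with the 6KR mutant of MED1, each as control or after hydrogen peroxide. RNA of the fruit fly Drosophila melanogaster was present in the libraries as a spike-in, per the labels. Groups and replicate numbers were taken from the sample titles, and the columns of the count table were matched to samples by those titles.

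The deposited values are raw counts per gene, whole numbers that were not normalized. They cover 25186 human genes named by Entrez identifier and 17453 fly genes named by FlyBase identifier, of which 2279 had a count in some library. STAR 2.5.2b, SAMtools 1.10, DESeq2 1.32.0 and the human build hg38 are named in the submitters' processing notes. The counting tool, its strand setting and the fly build are not given in the sources used here. Genes that overlap another gene, antisense genes and near-identical copies are therefore marked as uncertain where this was noticed. The marks may not be complete, so a gene without one may still share counts with a neighbour. Among the deposited counts of 1 to 4, between 68.4% and 74.8% were even in each library, against 49.5% to 51.5% among counts of at least 1000. As 2 counts may thus stand for 1 fragment, the counting interval given for a ratio was made from the summed counts divided by 2. The floors and that interval cover counting error alone.

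Total counts per library ranged from 79166272 to 103832756, with 87468 to 141804 fly counts. A floor of 3 counts corresponds to 0.0289 to 0.0380 CPM (counts scaled to an equal library total). Of the human identifiers 25081 were matched to symbols in the RefSeq gene table of the same human build, and the unmatched rows took at most 0.0664% of the human counts of a library. Gene positions are those of that table. Transcript lengths and GC content were medians over the transcripts of GENCODE release 29, found for 99.2% of the genes above 1 CPM. Transcripts encoded by the mitochondrial genome were not analysed here.

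The human counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter for the 4 groups (minimum count 10), which left 16419 genes. Libraries were scaled by the trimmed mean of M-values (TMM), and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, so that the groups share an estimate of the spread. The comparisons were 6KR against WT in control cells, 6KR against WT after peroxide, peroxide against control in WT cells, peroxide against control in 6KR cells, and the interaction, which is the peroxide response of 6KR cells minus that of WT cells. A gene was called where the two-sided p of edgeR, adjusted by Benjamini and Hochberg over all genes tested, was under 0.05. Replicates of a group were compared by a chi-square statistic of their counts, which was at least 5.23 per degree of freedom in every pair. This is spread beyond counting error and does not show whether the libraries are independent. Each library was taken as 1 sample.

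Before the data were examined, 22 gene lists with 581 entries were fixed. They were genes of the estrogen response, luminal identity, basal or mesenchymal cells, fibroblasts, p53 targets, NRF2 targets, antioxidant enzymes, ATF4 targets, endoplasmic reticulum (ER) stress, heat shock, metallothioneins, immediate early genes, NF-kB targets, interferon-stimulated genes, G1/S and replication, mitosis (G2/M), hypoxia and glycolysis, cholesterol synthesis, the BCL2 family, the Mediator complex, replication-dependent histones and mitochondrially encoded transcripts. The last of these was not analysed here, which left 21. Each list was tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, two-sided, and adjusted over the lists of a comparison. The same test with a correlation estimated from the data, and fry, were alternatives. Members called by edgeR were counted over all genes tested and after adjustment over the list alone.

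The genes named in each comparison were chosen by a rule fixed with the lists. It took a panel of 7 genes (MED1, ESR1, GREB1, TFF1, PGR, CDKN1A and HMOX1), whether called or not. It added the 6 highest and the 6 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups. From the 8 lists with the smallest camera p it took the 2 called members with the smallest p, and all called members of a list with at most 4. For the interaction the 5 highest and the 5 lowest were taken, over all libraries and without the condition on overlap. A gene named outside this rule is said to be so.

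Alternatives were size factors of the DESeq2 kind, library size alone, fly spike-in totals as library sizes, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a fold minimum of 2, the replicate number as a block, and leaving out each replicate. A fit without WT peroxide replicate 3 for all comparisons was added after the data were seen. In simulated counts for 6KR against WT in control cells (16182 genes), edgeR recovered 76% of the genes changed by 0.5 on the log2 scale and 98% of those changed by 1, and 5 of its 179 calls were unchanged genes.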

Results

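MCF7 is a human breast cancer cell line that carries the estrogen receptor and grows in response to estrogen. The cells compared here expressed ectopic MED1, a subunit of the Mediator complex, which links transcription factors at enhancers to RNA polymerase II. They carried either the wild-type protein (WT) or a mutant that the labels call 6KR, in a series on the acetylation of MED1 (K and R are the codes of lysine and arginine). Each line was sampled as control and after 0.5 mM hydrogen peroxide for 6 h, with 3 libraries in each of the 4 groups. Total counts per library lay between 79166272 and 103832756. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. In the text, ± is the SE for a log2 fold change and the SD for a level in CPM (counts scaled to an equal library total), with n = 3 libraries per group.

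The treatment and the MED1 form accounted for most of the spread between the libraries. Over genes above 1 CPM, the first principal component held 59.6% of the variance and parted peroxide from control libraries, and the second held 27.3% and parted 6KR from WT. Replicates correlated at r = 0.997 to 0.998 on the log2 CPM scale, except that WT peroxide replicate 3 correlated with its partners at r = 0.991 and 0.990. In that library ESR1 stood at 113 CPM against 154 and 157, PGR at 20.6 against 35.5 and 37.2, and TFF1 at 4734 against 3531 and 3454. Counts of called genes, and those of many lists, are given below also without it.

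Human counts per fly count measure human mRNA relative to the added fly RNA. Whether that RNA was added per cell or per amount of RNA is not given here, so the ratio is not read as mRNA per cell. Whether human reads were among the fly counts was not checked. WT control libraries held 999 ± 23.7 human counts per fly count and WT peroxide libraries 650 ± 55.7, a log2 difference of −0.62. In 6KR cells the ratio was 878 ± 14.5 in control and 701 ± 38.5 after peroxide, a log2 difference of −0.33. Each of these differences, and that between the lines in control cells (−0.19), had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. After peroxide the lines differed by 0.11, with an exact permutation p of 0.2. With fly totals as library sizes, the median log2 fold change of all genes lay at −0.20 for 6KR against WT in control cells and at 0.12 after peroxide. It lay at −0.59 for peroxide in WT cells, at −0.27 in 6KR cells and at 0.34 for the interaction, while with TMM scaling it was within 0.016 of 0 in each. The fold changes below are relative to the bulk of the human mRNA, and those with spike-in scaling are to be read against these medians.

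**Figure D1:**
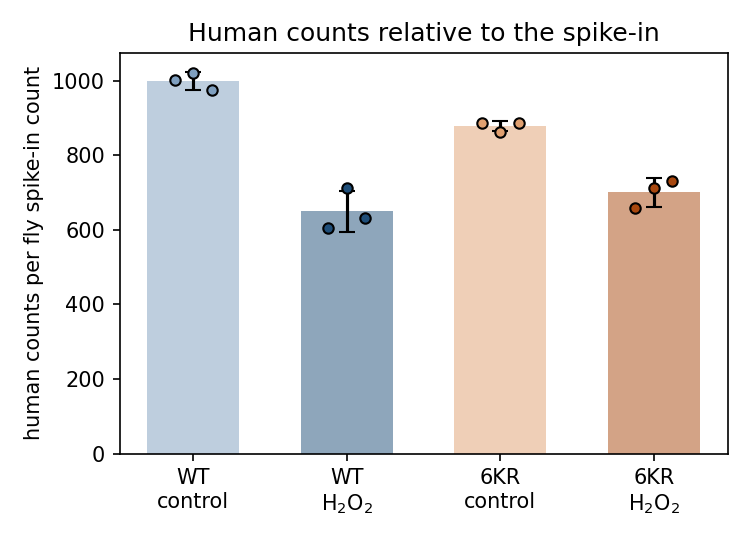
Human counts per fly spike-in count (y axis, linear, from 0) in the 4 groups. Points are libraries, bars the means and lines the SD of 3 libraries; the means fall from 999 to 650 in WT cells and from 878 to 701 in 6KR cells.

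How cells with 6KR MED1 differ from cells with WT MED1 was asked first in control cells. MED1 mRNA was 3.18-fold higher in the 6KR cells, at 3082 ± 16 CPM against 970 ± 13.9 (chromosome 17, 39404285 to 39451263, hg38). The position is that of the MED1 gene, and counts per gene do not separate ectopic from endogenous MED1 transcripts. MED1 protein was not measured here. Interferon-stimulated genes, which act in antiviral defence, were lower in the 6KR cells: 33 of 37 were called lower and 0 higher (34 lower adjusted over the list alone), with a median log2 fold change of −0.96 (list adjusted p = 0.0526 with an estimated correlation). Of 36 mitotic genes 19 and of 23 genes of cholesterol synthesis 9 were higher, and with spike-in scaling 2 were higher and 5 lower in each list. ESR1, the estrogen receptor gene, was 1.89-fold higher in the 6KR cells, and PGR, the progesterone receptor gene that estrogen induces, was 3.25-fold lower.

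In all, 5158 of 16419 genes were called, 2532 higher and 2626 lower in the 6KR cells, and 745 of them differed at least 2-fold (351 higher, 394 lower). With spike-in scaling the split was 778 higher and 5284 lower. When WT peroxide replicate 3, which is in neither group but adds to the shared spread, was left out of the fit, 7761 genes were called, 5149 of them among the 5158.

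Among the panel, ESR1 rose from 266 ± 3.78 to 502 ± 4.97 CPM and PGR fell from 45.1 ± 1.25 to 13.9 ± 0.685. CDKN1A, the p53 target that encodes the cell cycle inhibitor p21, was lower (−0.68 ± 0.04). The estrogen-induced genes TFF1 (−0.05 ± 0.09) and GREB1 (−0.18 ± 0.10) and the heme oxygenase gene HMOX1 (−0.17 ± 0.10) were not called. GREB1 and HMOX1 passed without WT peroxide replicate 3 in the fit, with edgeR adjusted p of 3.66e-06 and 0.0217. All 3 passed with spike-in scaling, at −0.26 (TFF1, edgeR adjusted p = 0.0165), −0.39 (GREB1, 0.00869) and −0.38 (HMOX1, 0.00753). Of 51 genes of the estrogen response 19 were higher and 14 lower (21 and 15 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.216). With spike-in scaling 13 of them were higher and 21 lower. PDZK1, an estrogen-induced scaffold gene, stood among the highest of all genes at 7.34-fold.

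The largest differences reached far beyond these genes. SOX11, a transcription factor gene, was 18.7-fold lower in the 6KR cells, at 1.23 ± 0.12 CPM against 23.1 ± 0.983. CPED1 was 8.67-fold lower, SLFN5 5.65-fold, FRY 4.46-fold, and HEY2, a target of Notch, 4.09-fold. FRY lies between 30000001 and 35000000 on chromosome 13 (hg38), a window whose 15 genes were all lower, with a median log2 fold change of −0.67. DHRS2 was 8.64-fold higher, the proteoglycan gene GPC6 9.19-fold, PADI3 8.47-fold and the long noncoding RNA LINC00052 5.83-fold. HCLS1, best known from blood cells, had 2698 counts in the 6KR control libraries and 11 in the WT control libraries (1 to 6 in each). Its ratio was 247, with a 95% counting interval of 116 to 837 when 2 counts are taken as 1 fragment.

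The interferon list held IFIT1 (−2.03 ± 0.16), RSAD2 (−2.52 ± 0.15) and IFI6, which fell from 520 ± 25.6 to 167 ± 20.7 CPM. Its camera adjusted p was 1.25e-23, and 0.0526 with an estimated correlation, as its members vary together (estimated correlation 0.331). RSAD2 overlaps its neighbour CMPK2, so its counts are uncertain. Of 36 mitotic genes 19 were higher and 2 lower (23 and 2 adjusted over the list alone), among them CCNB1 (0.34 ± 0.05) and PTTG1 (0.77 ± 0.09), with adjusted p = 0.0445 with an estimated correlation. Of 23 genes of cholesterol synthesis 9 were higher and 1 lower (12 and 2 over the list alone), with HMGCS1 at 0.57 ± 0.05 and FDFT1 at 0.46 ± 0.05. Of 26 genes of hypoxia and glycolysis 12 were higher and 2 lower (12 and 2 over the list alone), with NDRG1 at 0.79 ± 0.05 and PFKP at 0.46 ± 0.05. Both lists kept their call, at an adjusted p = 0.0445 with an estimated correlation. With spike-in scaling the medians of these 3 lists turned below 0, to −0.015, −0.0046 and −0.078, and stayed above the −0.20 of all genes. CCNB1 lost the call there (0.13, edgeR adjusted p = 0.234). Cholesterol genes without WT peroxide replicate 3 in the fit were higher in 13 cases and lower in 4, mitotic genes in 25 and 4 and hypoxia genes in 14 and 4.

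A further 4 lists were called with the preset correlation and lost the call with an estimated one. Of 18 basal or mesenchymal genes 8 were higher and 2 lower (9 and 2 adjusted over the list alone), with CD44 at 0.68 ± 0.05 and FN1 at 0.89 ± 0.11 (adjusted p = 0.0533 with an estimated correlation). Of 17 replication-dependent histone genes 9 were higher (9 over the list alone), with H2BC5 at 0.40 ± 0.07 and H2BC12 at 0.29 ± 0.05, both uncertain because near-identical copies exist (adjusted p = 0.07). Histone transcripts that are not polyadenylated are not meant to be covered by these libraries, so this list is uncertain as a measure of histone mRNA in every comparison. Of 20 heat shock genes 10 were higher and 2 lower (10 and 2 over the list alone), with HSPA4 at 0.25 ± 0.05 and HSPH1 at −0.42 ± 0.04 (adjusted p = 0.412), and with spike-in scaling their median of 0.19 became −0.020. Scaled so, H2BC5 (0.19, edgeR adjusted p = 0.118), H2BC12 (0.080, 0.534) and HSPA4 (0.046, 0.698) lost their calls. Heat shock genes were higher in 15 cases and lower in 3 without WT peroxide replicate 3 in the fit. HSPH1 lies in the window of chromosome 13 named above for FRY. The metallothionein list, of which 4 genes were tested, had 3 lower (3 over the list alone): MT2A at −1.23 ± 0.08, MT1X at −0.63 ± 0.11, and MT1F, all uncertain for near-identical copies (adjusted p = 0.07). Of 33 Mediator subunits 4, with MED1, were higher and 2 lower (4 and 2 over the list alone), 2 and 9 with spike-in scaling, and 6 and 7 without WT peroxide replicate 3 in the fit. Markers of luminal cells (5 of 20 higher, 8 lower; 6 and 8 over the list alone) and of fibroblasts (0 of 7 higher, 3 lower; 0 and 3 over the list alone) were not called as lists, with camera adjusted p = 0.155 and 0.0621. With spike-in scaling luminal genes were higher in 1 case and lower in 13.

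The same comparison after peroxide showed the interferon difference again and differences in stress and cell cycle genes. Interferon-stimulated genes were lower in 35 of 37 cases and higher in 0 (36 and 0 adjusted over the list alone), with a median of −1.37 and an adjusted p = 0.0321 with an estimated correlation. ATF4 targets, the genes of amino acid supply and stress that ATF4 induces, were lower in 25 of 31 cases and higher in 2 (25 and 2 over the list alone), with ASNS, the asparagine synthetase gene, at 104 ± 1.69 CPM against 206 ± 22.9. Mitotic genes were higher in 30 of 36 cases and lower in 0 (30 and 0 over the list alone), with a median of 0.45. MED1 was 3.25-fold higher and ESR1 2.40-fold higher in the 6KR cells.

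Here 6318 genes were called, 3398 higher and 2920 lower, 710 of them at least 2-fold. With spike-in scaling 4047 were higher and 1360 lower. Leaving out WT peroxide replicate 3, 7883 genes were called, 5965 of them among the 6318, and the interferon, ATF4 and mitotic lists had 36 lower, 25 lower and 33 higher.

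SOX11 (15.7-fold lower), CPED1 (13.0-fold lower), DHRS2 (10.8-fold higher), PADI3 (6.33-fold higher), PDZK1 (6.20-fold higher) and LINC00052 (5.16-fold higher) differed in the direction they had in control cells. HCLS1 was 15.4-fold higher, where its ratio was 247 in control cells. ACKR3, a chemokine receptor gene that estrogen regulates, was 5.29-fold higher. The remaining lowest genes were interferon-stimulated, namely RSAD2 (−3.25 ± 0.13), CMPK2 (−2.76 ± 0.17), whose span overlaps that of RSAD2, IFI44L (−2.58 ± 0.20) and IFIT3 (−2.44 ± 0.12). CDKN1A was 1.57-fold lower, at 937 ± 17.4 against 1471 ± 45.3 CPM, PGR was 2.94-fold lower and HMOX1 1.25-fold lower. TFF1 (−0.24 ± 0.09) passed the test by a small margin and lost the call without any of the 6KR peroxide replicates (edgeR adjusted p = 0.0646, 0.127 and 0.125). With spike-in scaling TFF1 (−0.12, edgeR adjusted p = 0.268) and HMOX1 (−0.21, 0.0978) lost their calls. GREB1 was at −0.03 ± 0.10 and not called, and it turned positive under spike-in scaling (0.077). It was called without WT peroxide replicate 3, at −0.20.

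The ATF4 list (median −0.42, adjusted p = 0.00499 with an estimated correlation), the mitotic list (0.00326) and the cholesterol list (0.00499) kept their calls with an estimated correlation. SESN2, a stress gene of the ATF4 and p53 lists, was at −0.83 ± 0.06, and PLK1 and NUSAP1, which serve mitosis, were at 0.69 ± 0.05 and 0.71 ± 0.05. Of 23 cholesterol genes 17 were higher and 1 lower (17 and 1 over the list alone), with HMGCS1 at 0.79 ± 0.05 and SQLE at 0.57 ± 0.04. Of 36 p53 targets 4 were higher and 17 lower (4 and 17 over the list alone), among them the decoy receptor gene TNFRSF10C, which was 5.06-fold lower (list adjusted p = 0.0722 with an estimated correlation). Of 31 immediate early genes 4 were higher and 19 lower (5 and 19 over the list alone), with EGR1 at −0.89 ± 0.06 and NR4A2 at 25.2 ± 2.12 against 50.5 ± 3.69 CPM (adjusted p = 0.0704 with an estimated correlation). Of 36 G1/S genes 18 were higher and 5 lower (18 and 6 over the list alone), with CDC25A at 0.69 ± 0.07 and CCNE1 at 0.62 ± 0.07 (adjusted p = 0.118 with an estimated correlation). Of 20 luminal genes 3 were higher and 9 lower (3 and 11 over the list alone), with ESR1 higher and MUC1 lower (−0.72 ± 0.05), and the call of the list ended with an estimated correlation (adjusted p = 0.0704) and without WT peroxide replicate 3 (camera adjusted p = 0.0986). The lists of hypoxia (9 of 26 higher, 3 lower; 10 and 3 over the list alone), the BCL2 family (2 of 15 higher, 7 lower; 2 and 7 over the list alone) and heat shock (9 of 20 higher, 1 lower; 11 and 1 over the list alone) were called with the preset correlation. Their adjusted p were 0.0704, 0.0786 and 0.46 with an estimated correlation. With spike-in scaling luminal genes were higher in 4 cases and lower in 2, p53 targets in 4 and 7, immediate early genes in 6 and 16, the BCL2 family in 2 and 3, G1/S genes in 20 and 1 and heat shock genes in 12 and 0. When WT peroxide replicate 3 was left out, luminal genes were higher in 6 cases and lower in 12 (median −0.16 before and −0.077 after), hypoxia genes in 14 and 4, heat shock genes in 14 and 2, and p53 targets in 4 and 24.

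**Figure D2:**
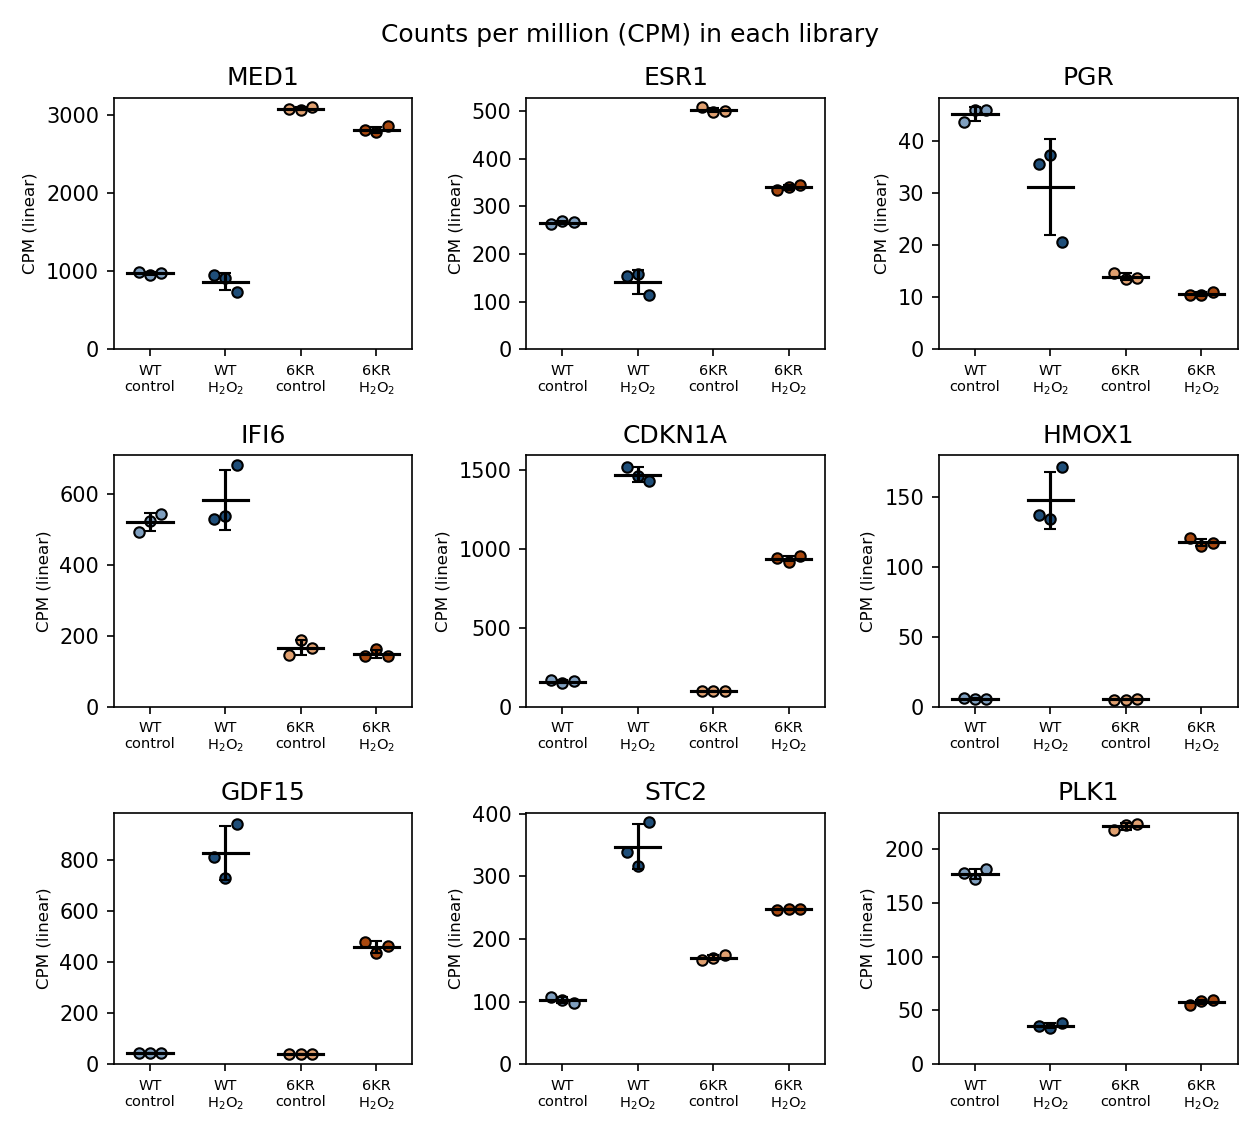
Level of 9 genes in CPM (y axes, linear, from 0) in each of the 12 libraries. Points are libraries, horizontal lines group means and vertical lines the SD of 3 libraries; MED1 lies near 3082 CPM in 6KR control cells and 970 CPM in WT control cells, and GDF15 reaches 826 CPM in WT and 459 CPM in 6KR cells after peroxide.

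What peroxide did was asked within each line. In WT cells targets of p53, the factor that answers DNA damage, rose together: 36 of 36 were higher (36 adjusted over the list alone), and CDKN1A rose 9.26-fold, from 159 ± 8.32 to 1471 ± 45.3 CPM. ATF4 targets (30 of 31 higher, 1 lower; 30 and 1 over the list alone) and NRF2 targets, the genes that answer oxidants (28 of 30 higher, 1 lower; 29 and 1 over the list alone), rose as well. HMOX1, an NRF2 target, rose 25.4-fold, from 5.79 ± 0.363 to 147 ± 20.7 CPM. Mitotic genes fell in 36 of 36 cases (36 over the list alone), by a median log2 fold change of −1.52, and genes of DNA replication and cholesterol synthesis fell too.

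In all 9175 genes were called, 4453 higher and 4722 lower, and of 2069 that changed at least 2-fold 1576 rose and 493 fell. With spike-in scaling 1359 were higher and 11288 lower, and the medians of the p53, ATF4 and NRF2 lists were 0.63, 0.70 and 0.30 where all genes had −0.59. Without WT peroxide replicate 3, 10275 genes were called, 8671 of them among the 9175, with 36 of 36 p53, 30 of 31 ATF4 and 27 of 30 NRF2 genes higher and 36 of 36 mitotic genes lower.

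GDF15, a secreted stress factor induced through p53 and ATF4, rose 18.9-fold, from 43.6 ± 1.61 to 826 ± 105 CPM. SLC7A11, the cystine transporter gene of the ATF4 and NRF2 lists, rose 13.4-fold, DDIT4 4.86-fold, and AKR1C2 7.01-fold, the last uncertain because AKR1C1 is nearly identical. Other genes among the highest were LHFPL3-AS2 (52.2-fold, an antisense gene and therefore uncertain), COL20A1 (20.8-fold), TNXB (20.6-fold, uncertain for its partial copy TNXA) and DNHD1 (16.3-fold). They started from 0.219 to 0.847 CPM in control cells. The p53, ATF4 and NRF2 lists had adjusted p of 0.000814, 0.000814 and 0.00193 with an estimated correlation.

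Immediate early genes rose in 23 of 31 cases and fell in 2 (23 and 2 over the list alone; adjusted p = 0.0161 with an estimated correlation), with FOSL1 at 3.49 ± 0.13 and DUSP4 at 1.35 ± 0.06. With spike-in scaling 10 of them were higher and 10 lower, and their median of 0.70 became 0.11. NF-kB targets rose in 8 of 13 cases and fell in 0 (8 and 0 over the list alone; 0.0167 with an estimated correlation), and genes of the BCL2 family in 11 of 15 with 1 lower (11 and 1 over the list alone; 0.0161 with an estimated correlation). The medians of the NF-kB and BCL2 lists, 0.52 and 0.39, became −0.066 and −0.21 with spike-in scaling, above the −0.59 of all genes. Interferon-stimulated genes rose in 32 of 37 cases and fell in 0 (32 and 0 over the list alone), with RSAD2 at 2.01 ± 0.12 and IFIT3 at 1.75 ± 0.12. Their list lost its call with an estimated correlation (adjusted p = 0.112), and with spike-in scaling 9 were higher and 8 lower. Basal or mesenchymal genes rose in 10 of 18 cases and fell in 2 (10 and 2 over the list alone; 0.0228 with an estimated correlation), while with spike-in scaling 3 were higher and 7 lower, and their median of 0.63 became 0.032. Of 23 antioxidant enzymes 10 rose and 3 fell (10 and 3 over the list alone; adjusted p = 0.414 with an estimated correlation, 0.105 by camera without WT peroxide replicate 3). Their median of 0.13 became −0.021 without that library and −0.47 with spike-in scaling.

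Among the genes that fell, PLK1, a mitotic kinase gene, dropped from 177 ± 4.64 to 35.7 ± 2.2 CPM and CENPE, a kinetochore motor gene, from 76.4 ± 0.466 to 15.1 ± 0.772. PIF1, a helicase gene, was 9.18-fold lower, TNFAIP8L1 5.86-fold, B3GALT5 5.70-fold and ADAMTS9 5.11-fold. G1/S and replication genes fell in 35 of 36 cases (35 over the list alone), with MCM10 at −1.27 ± 0.05 and CDC6 at −0.97 ± 0.04, and cholesterol genes in 20 of 23 (22 over the list alone), with SQLE at −0.94 ± 0.04 and HMGCS1 at −0.86 ± 0.05. The mitotic, G1/S and cholesterol lists had adjusted p of 0.000246, 0.000814 and 0.000814 with an estimated correlation. Of 51 estrogen response genes 12 rose and 28 fell (12 and 29 over the list alone). That list lost its call with an estimated correlation (adjusted p = 0.0841) and without WT peroxide replicate 3 (camera adjusted p = 0.0558). ESR1 (−0.91 ± 0.09), GREB1 (−0.61 ± 0.10) and PGR (−0.54 ± 0.15) fell. TFF1 rose by 0.26 ± 0.09 and fell by 0.34 with spike-in scaling, and it lost the call without WT control replicate 1 or 2 (edgeR adjusted p = 0.0751 and 0.0794). MED1 (−0.17 ± 0.07) passed with an edgeR adjusted p of 0.0494 and lost the call without any WT control replicate (edgeR adjusted p = 0.113, 0.0759 and 0.096). It also lost the call with size factors of the DESeq2 kind (edgeR adjusted p = 0.0692), library size alone (0.131), a filter of 1 CPM in 3 libraries (0.115) and a fit of only the groups compared (0.197). The same held with DESeq2 (DESeq2 adjusted p = 0.0752). ER stress genes (2 of 19 higher, 11 lower; 2 and 11 over the list alone), heat shock genes (4 of 20 higher, 4 lower; 3 and 4 over the list alone) and hypoxia genes (10 of 26 higher, 8 lower; 10 and 8 over the list alone) were not called as lists (camera adjusted p = 0.0627, 0.948 and 0.814). ER stress genes passed without WT peroxide replicate 3 (camera adjusted p = 0.00899; 3 higher, 13 lower), where heat shock genes were higher in 5 cases and lower in 9. With spike-in scaling ER stress genes were higher in 0 cases and lower in 17, heat shock genes in 2 and 17, hypoxia genes in 1 and 20 and estrogen response genes in 4 and 42.

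**Figure D3:**
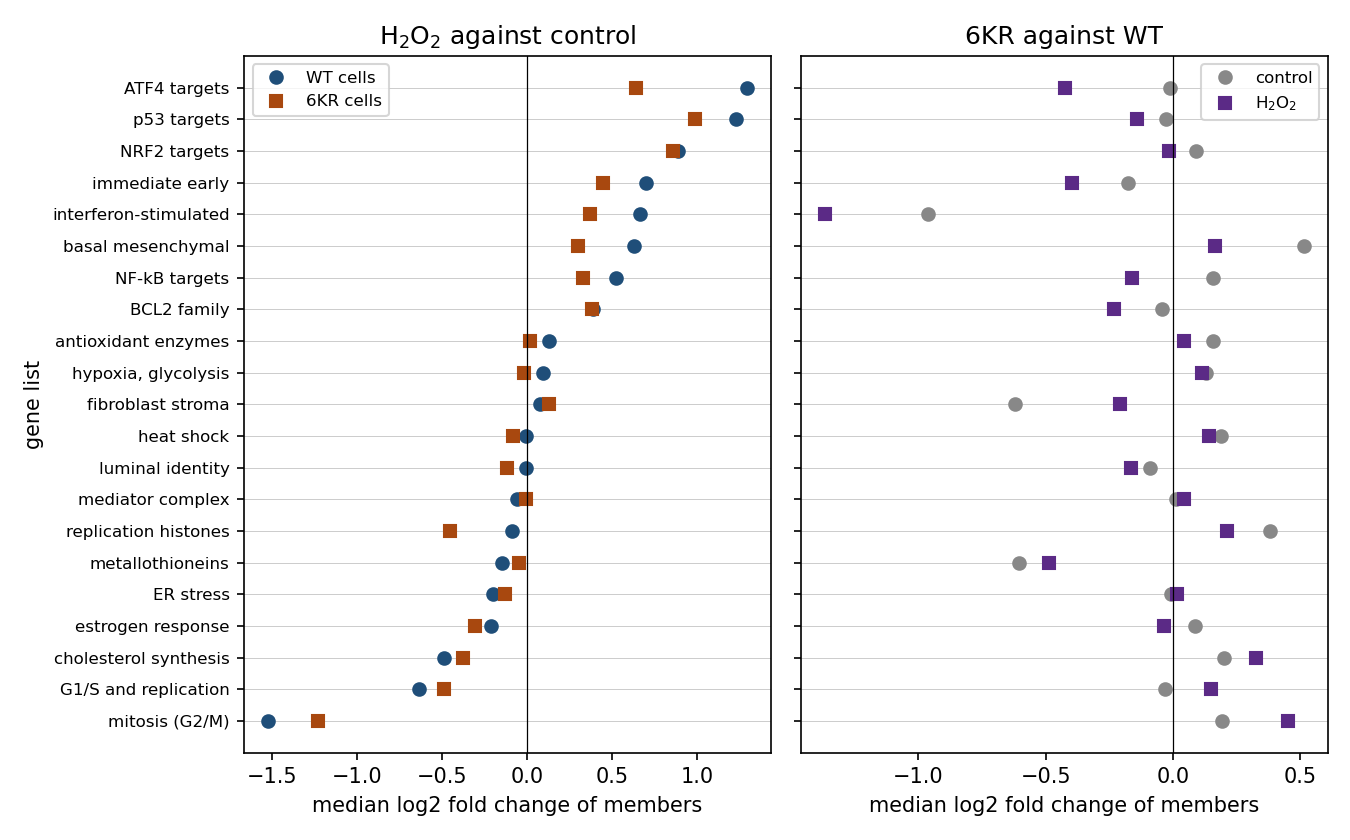
Median log2 fold change (x axes) of the members of 21 gene lists (y axis) for peroxide against control in both lines (left) and for 6KR against WT in both treatments (right). With TMM scaling the ATF4 list lies at 1.30 in WT and 0.64 in 6KR cells on the left, and the interferon list at −0.96 and −1.37 on the right.

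In 6KR cells all 36 p53 targets rose (36 adjusted over the list alone), with CDKN1A up 9.48-fold, from 98.8 ± 1.55 to 937 ± 17.4 CPM. NRF2 targets rose in 26 of 30 cases and fell in 0 (26 and 0 over the list alone), with HMOX1 up 22.8-fold, and ATF4 targets in 25 of 31, with 0 lower (26 and 2 over the list alone) and a median of 0.64. Mitotic genes fell in 36 of 36 cases (36 over the list alone), by a median of −1.23, and G1/S genes in 33 of 36 (33 over the list alone). Cholesterol genes fell in 21 of 23 (21 over the list alone).

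Here 7292 genes were called, 3589 higher and 3703 lower, with 1182 of them up and 205 down at least 2-fold. With spike-in scaling 1623 were higher and 7699 lower, and with library size alone 4269 were higher and 2925 lower. Without WT peroxide replicate 3 in the shared fit 9542 were called, 7270 of them among the 7292, with 36 p53, 29 NRF2 and 27 ATF4 genes higher and 36 mitotic genes lower.

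GDF15 rose 11.4-fold, to 459 ± 22.2 CPM, SLC7A11 9.67-fold, FOSL1 9.05-fold, AKR1C2 6.92-fold (uncertain, as above) and DDIT4 3.26-fold. INPP5D, a phosphatase gene, rose 15.5-fold, DNHD1 11.5-fold, and CYP1A1, the cytochrome gene induced by the aryl hydrocarbon receptor, 9.94-fold, while SMIM10L2A (10.5-fold) is uncertain because a near-identical copy exists. The genes that fell most were PIF1 (8.45-fold lower), TNFAIP8L1 (4.87-fold) and the mitotic genes KIF20A (4.09-fold), PLK1 (3.82-fold), HMMR (3.42-fold) and DLGAP5 (3.41-fold). UHRF1 (−0.97 ± 0.06), MCM6 (−0.65 ± 0.04), SQLE (−0.68 ± 0.04) and HMGCS1 (−0.63 ± 0.05) fell with their lists. With an estimated correlation the p53, NRF2, ATF4, mitotic, G1/S and cholesterol lists had adjusted p of 0.000732, 0.00127, 0.00257, 9.65e-05, 0.00126 and 0.000732. Of 31 immediate early genes 22 rose and 2 fell (22 and 2 over the list alone; 0.0187 with an estimated correlation), JUN among them (0.55 ± 0.04). Interferon-stimulated genes rose in 16 of 37 cases and fell in 0 (16 and 0 over the list alone), with an adjusted p = 0.441 with an estimated correlation. NF-kB targets (8 of 13 higher, 0 lower; 8 and 0 over the list alone) and the BCL2 family (10 of 15 higher, 1 lower; 12 and 2 over the list alone) kept their calls, with adjusted p of 0.0273 and 0.0114 with an estimated correlation. Basal or mesenchymal genes (7 of 18 higher, 1 lower; 8 and 1 over the list alone) lost theirs (0.0598), also without WT peroxide replicate 3 in the fit (camera adjusted p = 0.0635; 10 higher, 2 lower). Of 23 antioxidant enzymes 7 rose and 4 fell (7 and 4 over the list alone), and the list was not called (camera adjusted p = 0.197). With spike-in scaling the medians of the immediate early, NF-kB, BCL2, interferon and basal lists were 0.18, 0.055, 0.11, 0.098 and 0.033, where all genes had −0.27.

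Of 51 estrogen response genes 6 rose and 25 fell (7 and 27 adjusted over the list alone; adjusted p = 0.0091 with an estimated correlation), with MYB at −0.74 ± 0.05 and ELOVL2 at −1.09 ± 0.07. ESR1 (−0.56 ± 0.09) and GREB1 (−0.46 ± 0.10) fell. MED1 (−0.13 ± 0.07), PGR (−0.39 ± 0.16) and TFF1 (0.07 ± 0.09) were not called, and TFF1 turned to −0.21 with spike-in scaling, where it passed, as did MED1 (−0.41, edgeR adjusted p = 0.000442) and PGR (−0.66, 0.000595). With that scaling 3 of the 51 were higher and 35 lower, and without WT peroxide replicate 3 in the fit 11 and 28. All 3 genes passed without WT peroxide replicate 3 in the shared fit, with edgeR adjusted p of 1.74e-06, 1.67e-06 and 0.0431.

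Whether the peroxide response itself differed between the lines was tested with the interaction, the response of 6KR cells minus that of WT cells. ATF4 targets rose less in 6KR cells: 21 of 31 were called lower and 0 higher (27 and 0 adjusted over the list alone), with a median of −0.47. STC2, a secreted glycoprotein gene, rose by 1.76 ± 0.06 on the log2 scale in WT cells and by 0.54 ± 0.06 in 6KR cells (interaction −1.22 ± 0.09; chromosome 5, 173314723 to 173328414, hg38). ALDH1L2, a mitochondrial folate enzyme gene, differed alike (−1.21 ± 0.12). Mitotic genes fell less in 6KR cells, with 13 of 36 higher and 1 lower (24 and 1 over the list alone) and a median of 0.25. Most other genes did not pass this test.

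In all 475 genes were called, 263 higher and 212 lower, and 40 of them at least 2-fold. The count was 1812 without WT peroxide replicate 3, with all 475 among them, and 27 of 31 ATF4 genes were lower and 24 of 36 mitotic genes higher. Without WT peroxide replicate 2 it was 774. Without WT control replicate 1, 2 or 3 it was 226, 215 or 182, without a 6KR control replicate 281, 182 or 187, and without a 6KR peroxide replicate 222, 191 or 183. With spike-in scaling 5451 genes were higher and 68 lower, the ATF4 list had a median of −0.16 and the mitotic list one of 0.57, where all genes had 0.34. Of the ATF4 list 7 were lower and 0 higher so scaled, and of the mitotic list 33 higher and 0 lower.

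GDF15 (−0.73 ± 0.10), FAS (−0.69 ± 0.10) and 4 more of 36 p53 targets were lower and 0 higher (12 and 0 over the list alone; 1 higher and 16 lower without WT peroxide replicate 3, 5 higher and 1 lower with spike-in scaling), while CDKN1A was at 0.03 ± 0.06 and not called. G1/S genes were higher in 9 of 36 cases and lower in 0 (16 and 0 over the list alone), with MCM10 at 0.50 ± 0.07 and CDC6 at 0.42 ± 0.06, and the mitotic genes CENPE and MKI67 were at 0.59 ± 0.07 and 0.47 ± 0.06. Of 23 cholesterol genes SQLE (0.26 ± 0.06) and INSIG1 (0.39 ± 0.08) were higher and 0 lower (3 and 0 over the list alone). SQLE lost the call without any 1 replicate other than WT peroxide replicate 2 or 3 (edgeR adjusted p = 0.071 to 0.168) and without a filter on low counts (0.0873). INSIG1 lost it without any 1 replicate other than 6KR control replicate 1 and WT peroxide replicates 2 and 3 (0.0513 to 0.088). With an estimated correlation the ATF4, mitotic, G1/S, cholesterol and p53 lists had adjusted p of 0.000491, 0.00122, 0.00518, 0.0184 and 0.0304. Of 8 lists called with the preset correlation alone 3 were the immediate early genes (0 higher and 6 lower of 31, 1 and 8 over the list alone, with DUSP4 and FOSL2) and the NRF2 targets (0 higher and 1 lower of 30, 0 and 4 over the list alone, with OSGIN1) and the interferon-stimulated genes (0 higher and 2 lower of 37, 0 and 13 over the list alone, with OASL and IFITM1). Their adjusted p with an estimated correlation were 0.0565, 0.0915 and 0.136. The other 5 were the estrogen response (1 higher and 4 lower of 51, 1 and 5 over the list alone), basal or mesenchymal genes (0 and 0 of 18, 0 and 4 over the list alone), NF-kB targets (0 and 0 of 13, 0 and 3 over the list alone), histones (0 and 1 of 17, 0 and 2 over the list alone) and antioxidant enzymes (0 and 0 of 23, 0 and 0 over the list alone). These had adjusted p of 0.0565 with an estimated correlation, and the antioxidant enzymes 0.414. When WT peroxide replicate 3 was left out, G1/S genes were higher in 21 cases and lower in 0, cholesterol genes in 9 and 0, immediate early genes in 0 and 12, NRF2 targets in 1 and 6, interferon-stimulated genes in 0 and 17, the estrogen response in 4 and 12, basal genes in 0 and 2, NF-kB targets in 0 and 3, histones in 1 and 2, and antioxidant enzymes in 0 and 1. Among the genes just named, FOSL2 lost the call without 6KR peroxide replicate 2 (edgeR adjusted p = 0.0532) or WT control replicate 3 (0.0505). OSGIN1 lost it without 6KR peroxide replicate 2 or 3, 6KR control replicate 3 or WT control replicate 2 or 3 (0.0507 to 0.0562). OASL lost it without any 1 replicate other than 6KR peroxide replicate 2 and WT peroxide replicates 2 and 3 (0.0514 to 0.104), and IFITM1 without any 6KR peroxide replicate, 6KR control replicate 2 or 3 or WT control replicate 1 or 2 (0.0728 to 0.118). With spike-in scaling the medians of the p53, immediate early, NRF2 and interferon lists were positive (0.16, 0.15, 0.21 and 0.039), below the 0.34 of all genes. So were those of the estrogen (0.25), basal (0.11), NF-kB (0.15), histone (0.037) and antioxidant lists (0.22). Scaled so, FAS (−0.37, edgeR adjusted p = 0.0637), DUSP4 (−0.19, 0.28), FOSL2 (−0.082, 0.636), OSGIN1 (−0.23, 0.157), OASL (−0.26, 0.223) and IFITM1 (−0.13, 0.446) lost their calls.

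**Figure D4:**
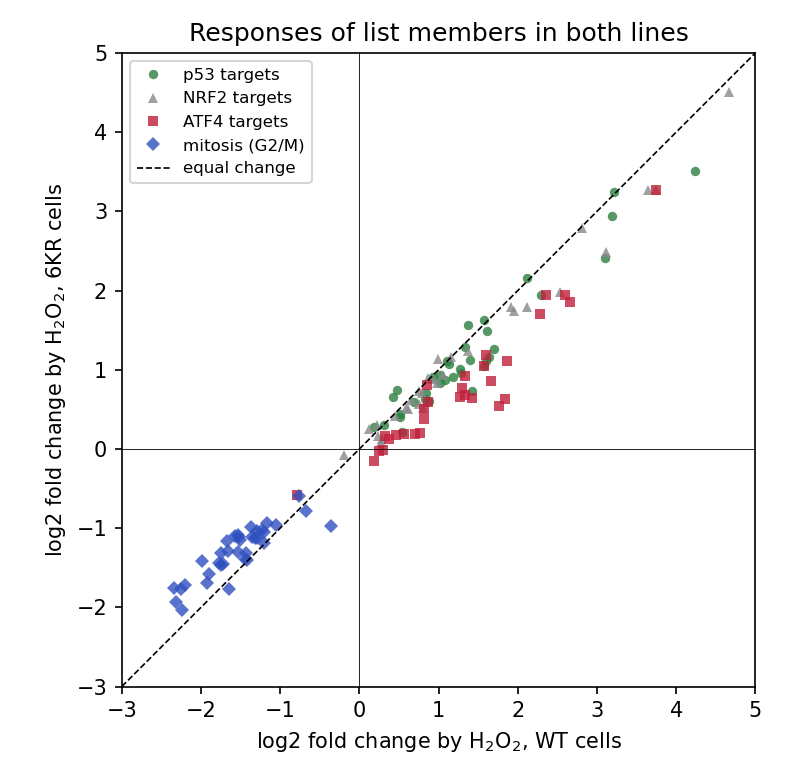
Log2 fold change by peroxide in WT cells (x axis) against that in 6KR cells (y axis) for members of 4 gene lists, with TMM scaling; the dashed line marks equal change. The median of the ATF4 list is 1.30 in WT and 0.64 in 6KR cells, and that of the p53 list 1.23 and 0.99.

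Among the highest called genes were GHR (1.11 ± 0.17), PCDH19 (1.08 ± 0.21), ADAMTS9 (1.04 ± 0.11), E2F8 (0.97 ± 0.20) and ANK1 (0.95 ± 0.20). E2F8 lost the call without any 6KR peroxide replicate, 6KR control replicate 2 or 3 or WT control replicate 2 or 3 (edgeR adjusted p = 0.0543 to 0.0655). ANK1 lost it without 6KR peroxide replicate 1 or 3, 6KR control replicate 1 or 3 or WT control replicate 1 (0.0653 to 0.0699), and PCDH19 without 6KR peroxide replicate 2 (0.0522). The lowest were HCLS1, RN7SK, STC2, ALDH1L2 and NAV2 (−1.05 ± 0.14). The fitted value of HCLS1 rests on 11 counts in the WT control libraries. RN7SK (−2.21 ± 0.47), of which many near-identical copies exist, lost the call without any 6KR peroxide or WT control replicate (edgeR adjusted p = 0.0509 to 0.072). In 6KR control replicate 2 it stood at 34.4 CPM against 11.5 and 11.6, and the difference was −1.52 without that library. RN7SK transcripts that are not polyadenylated are not meant to be covered by these libraries, so its level is uncertain for this too. Of the panel, MED1 (0.03 ± 0.10), ESR1 (0.35 ± 0.13), GREB1 (0.15 ± 0.15), PGR (0.15 ± 0.22), HMOX1 (−0.16 ± 0.13) and TFF1 (−0.19 ± 0.13) were not called, and HMOX1 and TFF1 turned positive with spike-in scaling (0.17 and 0.13). With that scaling MED1 (0.35, edgeR adjusted p = 0.0379), ESR1 (0.66, 0.00555), GREB1 (0.47, 0.0304) and CDKN1A (0.36, 0.0244) passed. ESR1 passed without WT peroxide replicate 3, at 0.21 with an edgeR adjusted p of 0.000215.

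Across the 16419 genes the log2 fold changes by peroxide in the lines correlated at r = 0.842 (genes are not independent replicates), and the slope of the 6KR on the WT response was 0.735. The slope of the WT on the 6KR response was 0.965. Noise in the fold changes lowers both slopes, so 0.735 is not a measure of how much smaller the 6KR response was. Both lines shared 3024 genes called higher, where independent lists would share 973, and 3252 called lower, where they would share 1065, while 23 were called in opposite directions. The comparisons have no library in common. The differences between 6KR and WT in control cells and after peroxide correlated at r = 0.599, with 1781 genes called higher in both (524 for independent lists), 1801 lower in both (467) and 38 in opposite directions.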

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

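The tests of WT peroxide replicate 3 as a cause, of a uniformly smaller response, of list medians under spike-in scaling, and the permutation of residuals were chosen only after the results they bear on had been seen. Each result given here was singled out because the peroxide response of the 6KR cells differed from that of the WT cells in a test of the difference itself.

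The response of 475 genes differed between the lines. Among 100 draws of other assignments of the MED1 form within each treatment, the real one included, 10 gave as many genes, so chance cannot be excluded by this count, and the highest other count was 7802. Of the 9 others 1, that with 7802 genes, kept the lines whole in both treatments and exchanged them in 1, and 8 kept them whole in 1 treatment and mixed them in the other. This points to a structure of the samples: such a draw turns all or part of the difference between the lines into an interaction. The 75 draws that mixed the lines in both treatments gave at most 0 genes. Such a draw puts libraries of both lines into the same group and widens its spread, so few calls were bound to follow. No conclusion is drawn from these draws. In place of labels, residuals of a limma fit without interaction were also permuted, on voom values without their weights. The real arrangement gave 313 genes and the highest of the others 4, so that 1 of 100 was as large. This fit is neither the edgeR fit that called 475 genes nor the limma-voom alternative, which called 471. Its residuals still hold any interaction and the deviation of WT peroxide replicate 3. Moving them between groups widens the spread within groups, which makes low counts in the other draws likely in advance. For each of the direct comparisons the 10 splits of 6 libraries are too few for a share under 0.05: the real counts were 5158, 6318, 9175 and 7292, the highest other count was 0 in each, and 1 split, the real one, was as large. The other splits also mix the groups compared and so widen the spread, which makes a count near 0 likely in advance.

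The ATF4 list had a median difference in response of −0.47, and the medians were positive, 0.25 for mitosis, 0.18 for G1/S and 0.13 for cholesterol synthesis, in 3 of the lists that peroxide lowered. Called lower without WT peroxide replicate 3 were 27 ATF4 members, which argues against that library as the cause. A change of scaling shifts all genes alike, so the distance of the ATF4 median from that of all genes (−0.50 with spike-in scaling) does not bear on the scaling as the cause, although this distance had been chosen beforehand to decide it. With spike-in scaling the ATF4 median itself was −0.16 (95% interval −0.38 to 0.04, from members and the spread of the spike-in ratios). Of 31 members 7 were called lower and 0 higher there, where 68 of 16419 genes were lower. Whether the list as a whole rose less per unit of spike-in, or only relative to other genes, stays open. The mitotic median was 0.57 (0.39 to 0.77). As spike-in scaling raised the interaction of all genes by 0.32 and the mitotic median was 0.25 before, a value above 0 was bound to follow. It therefore does not decide whether the scaling is the cause of the smaller fall of mitotic genes, though the median was above 0 with both scalings. The slope of the 6KR on the WT response was 0.579 over 29 ATF4 members and 0.885 over 64 p53 and NRF2 members. The difference was −0.31 (95% bootstrap interval −0.38 to −0.20, and −0.46 to −0.15 when widened for the correlation between members). The 2 genes that the ATF4 list shares with those lists, SLC7A11 and SESN2, were left out. SLC7A11 rose by 3.75 in WT and 3.27 in 6KR cells, so the ATF4 slope would be higher with it, by an amount not computed here. For the members compared, the difference argues against a response smaller by the same share in the ATF4 list as in the p53 and NRF2 lists. Other lists that rose were not compared so. Their medians in WT and 6KR cells were 0.67 and 0.37 (interferon), 0.70 and 0.45 (immediate early), 0.52 and 0.33 (NF-kB), 0.63 and 0.30 (basal) and 0.39 and 0.38 (BCL2 family). For mitotic genes the slope was 0.825, a difference of −0.060 from the p53 and NRF2 lists (−0.11 to −0.0092, and −0.16 to 0.039 when so widened), so a response that is smaller by a like share stays open for them. Over genes above 1 CPM and without each library in turn the differences were −0.27 to −0.25 and −0.075 to −0.059. The slopes are those with TMM scaling. They run through the origin, unlike the slope of 0.735 over all genes, and are not to be compared with it. A weaker ATF4 response in 6KR cells is a hypothesis, and it may reflect the higher MED1 mRNA level of these cells (log2 difference 1.67), which the design does not part from the mutation.

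Other lists whose response differed were p53 targets (median −0.16), NRF2 targets (−0.12), antioxidant enzymes (−0.11), basal or mesenchymal genes (−0.21), estrogen response genes (−0.064), replication-dependent histones (−0.30), immediate early genes (−0.17), interferon-stimulated genes (−0.29) and NF-kB targets (−0.18). Of the 13 lists 5 kept the call with an estimated correlation, namely those of ATF4, mitosis, G1/S, cholesterol synthesis and p53. The 8 others had adjusted p of 0.0915 (NRF2), 0.414 (antioxidant enzymes), 0.136 (interferon) and 0.0565 (the remaining ones) with an estimated correlation. The antioxidant list had a camera adjusted p of 0.397 without WT peroxide replicate 3 and of 0.0635 to 0.134 without any other replicate except 6KR control replicate 2 and WT peroxide replicates 1 and 2. The basal list had 0.053 without WT peroxide replicate 1. Without WT peroxide replicate 3 the medians of the antioxidant, NRF2, histone and immediate early lists were 0.011, −0.060, −0.12 and −0.26. The medians of the 9 lists named first in this paragraph were above 0 with spike-in scaling (0.037 to 0.25). The histone list is uncertain throughout, as histone transcripts that are not polyadenylated are not meant to be covered.

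Among named genes the log2 response of the 6KR cells exceeded that of the WT cells by 1.11 for GHR, 1.08 for PCDH19, 1.04 for ADAMTS9, 0.97 for E2F8, 0.95 for ANK1, 0.59 for CENPE, 0.50 for MCM10, 0.47 for MKI67, 0.42 for CDC6, 0.39 for INSIG1 and 0.26 for SQLE. The difference was −3.98 for HCLS1, which rests on 11 counts in the WT control libraries, and −2.21 for RN7SK, which was −1.52 without 6KR control replicate 2. It was −1.22 for STC2, −1.21 for ALDH1L2, −1.05 for NAV2, −0.73 for GDF15, −0.69 for FAS, −0.58 for OASL, −0.56 for OSGIN1, −0.52 for DUSP4, −0.45 for IFITM1 and −0.40 for FOSL2. IFITM1 has near-identical relatives and is uncertain. RN7SK is uncertain for its copies, and because transcripts that are not polyadenylated are not meant to be covered. The calls of PCDH19, E2F8, ANK1, INSIG1, SQLE, RN7SK, OASL, OSGIN1, IFITM1 and FOSL2 each ended without some 1 replicate, with edgeR adjusted p of 0.0505 to 0.168.

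The fall of the human to fly ratio was smaller in 6KR cells by 0.30 on the log2 scale (SE 0.09, n = 3 libraries per group). It was singled out by a two-sided t test of the difference with 4.03 degrees of freedom, which rests on normal log2 ratios, and no exact test of the difference was available.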

How the results depend on the processing

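The alternative without WT peroxide replicate 3 in the shared fit was chosen after the data were seen. With a fold minimum of 2 the counts of called genes were 745 and 710 for 6KR against WT in control and peroxide cells, 2069 and 1387 for peroxide in WT and 6KR cells, and 40 for the interaction, fewer by construction. For the interaction spike-in scaling called 5519 genes and DESeq2 956, and leaving out 1 replicate gave 182 to 1812. The count for 6KR against WT in control cells was 7761 without WT peroxide replicate 3 in the fit. Where the spread is shared, that library adds to it, and the cause of the other shifts was not tested. With spike-in scaling the sign reversed for GREB1 in 6KR against WT after peroxide (0.077), TFF1 by peroxide in WT (−0.34) and 6KR cells (−0.21), and the interactions of HMOX1 (0.17) and TFF1 (0.13). Leaving out 1 replicate gave −0.20 to 0.053 for GREB1 in 6KR against WT after peroxide, and for interactions −0.0047 to 0.25 for GREB1, −0.077 to 0.29 for PGR, −0.0015 to 0.074 for CDKN1A and −0.067 to 0.073 for MED1. As a correlation, the similarity of the hydrogen peroxide responses was 0.924 with a filter of 1 CPM in 3 libraries and 0.820 to 0.839 without 1 replicate. The slope of the 6KR response on the WT response was 0.779 and 0.678 to 0.762.

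Of 117 values of named genes called in the direct comparisons, 3 were lost without some replicate, 6 under spike-in scaling and 3 under another setting, and of 23 in the interaction 10, 6 and 3. Of 57 list calls 32 held with an estimated correlation. Of the 57, fry lost 3, and it called 26 that camera did not. Among these were the estrogen response for 6KR against WT in control cells (fry adjusted p = 4.47e-05) and ER stress by peroxide in WT cells (fry adjusted p = 9.4e-06). With the replicate number as a block 4995, 6181, 9087, 7122 and 349 genes were called, 0 of the list calls were lost, and of the named genes OASL was (edgeR adjusted p = 0.0609, interaction). Of 18 same-numbered pairs 1 correlated above 0.1 (−0.126 to 0.146), and 6 of 12 libraries correlated best with their own number. No clear pairing by number was seen, and these values do not settle whether the numbers pair the libraries. A fit of only the groups compared gives no separate value for the interaction, which uses all groups. Genes near 3 counts are limited by depth.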

Other observations

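The tests of neighbouring genes, of the MED1 level, and of a joint trend in GC content and transcript length were chosen only after the results they bear on had been seen. Genes that differed between 6KR and WT cells were grouped along some chromosomes. On chromosome 13 the 15 genes between 30000001 and 35000000 (hg38) had a median log2 fold change of −0.67 in control cells and −0.57 after peroxide, and 100% of them were lower in the 6KR cells. FRY and HSPH1, named earlier, lie there. In control cells FRY (−2.16) differed by more than that median and HSPH1 (−0.42) by less, so HSPH1 cannot be told apart from its window. The 17 genes between 95000001 and 100000000 of the same chromosome had medians of 0.59 and 0.78, and 100% were higher. On chromosome 9 the 76 genes between 135000001 and 140000000 had medians of −0.38 and −0.42, with 98.7% lower, and on chromosome 8 the 16 genes between 65000001 and 70000000 had medians of 0.45 and 0.43, with 100% higher. Of 418 windows of 5 Mb, 17 had a median over 0.3 in size. The windows given above were chosen for their size after their values were seen. MUC1 and PTTG1, named earlier, lie in windows with smaller medians in control cells and after peroxide. These were −0.29 and −0.32 on chromosome 1 (155000001 to 160000000) and 0.24 and 0.19 on chromosome 5 (160000001 to 165000000). MUC1 after peroxide (−0.72) and PTTG1 in control cells (0.77) differed by more than those medians.

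A hypothesis is that the cell populations may differ in copy number at these places, apart from their MED1 form. Windows of 5 Mb took 19.7% of the variance of the called genes in control cells (adjusted R squared 0.197, highest of 200 shuffles 0.0273), and 6.56% and 5.12% for peroxide in WT and 6KR cells. For 704 of the 745 genes that differed at least 2-fold, the neighbours in the same window had a median log2 fold change of 0.021 in the gene's direction (95% bootstrap interval 0.0087 to 0.029), which argues against copy number changes of about a window's size as the cause of most differences among these 704. Smaller changes of copy number, and the 41 other genes, were not tested. No DNA was analysed here, so copy number and the effect of the MED1 form cannot be told apart for the smaller differences. The same holds for the higher MED1 mRNA of the 6KR cells (log2 difference 1.67), which goes with the mutant in every library.

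WT peroxide replicate 3 stood apart from its partners, with a chi-square per degree of freedom of 94.4 and 104 against at most 10.7 elsewhere. Its deviation correlated across genes with transcript length at a Spearman rho of −0.18 (at most 0.075 in size in the other 3 groups), a stronger length trend than theirs. With GC content it correlated at 0.31 (at most 0.405), so libraries that do not stand apart had rank correlations as large. The SD of its deviation was 0.301 against at most 0.137 there, so a like correlation can stand for a larger trend in log2 units. After a joint trend in both was removed, which took 14.7% of the variance, the SD of its deviation was 0.278 against at most 0.137 in the other 3 groups, which argues against that trend as the whole cause, though it may account for part. The deviation had a rho of 0.012 with the peroxide response of the 6KR cells, which argues against a response further advanced or weaker by a like share in all genes. On the first principal component, however, this library lay farther from the control libraries (42.5) than its partners (38.6 and 36.4). A response that is further advanced in some genes, or at another stage, therefore stays open. The cause stays open: a difference in handling of this sample was not tested, as the labels record none.

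In that library 15 of 20 heat shock genes (median deviation 0.21) and 17 of 23 antioxidant genes (0.13) lay above the partner libraries. So did 18 of 29 NRF2 targets (0.12) and 12 of 20 luminal genes (0.13). Of p53 targets 12 of 36 (−0.08) lay above and of immediate early genes 9 of 30 (−0.10), where 6139 of 12821 genes in all did (−0.02). The lists were not tested for these deviations.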
